A study of Mus musculus with 2 samples.

How the data were processed

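Adult mouse cochlear explants were profiled by 10x 3' single-cell RNA sequencing (kit version 3.1, 150 bp reads) in 2 libraries. The cocktail library and the vehicle library each pooled 5 cultures by the labels, after digestion in 0.25% trypsin for 15 min at 37 °C, and about 1400 and about 1700 cells were stated. Vehicle was sterile water with 0.1% DMSO. The deposited matrices hold raw UMI counts per gene and cell barcode for 31053 genes. Cell Ranger 5.0.0 made them per the file headers. The submitters' processing notes also name Cell Ranger 5.0, STAR, Seurat 3.2.2 and the builds mm10 and GRCm38, without the role of each or the annotation release. No genome sequence or reads were at hand. Gene positions came from GENCODE M21, which held 31011 of the 31053 gene identifiers.

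Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which removed 74 cocktail and 104 vehicle barcodes. Doublets were called per library with Scrublet, which called 0 and 2 cells, and these were removed. Doublets of similar cells are not found in this way and remain uncounted. Free RNA was not subtracted. Both libraries were clustered together without batch integration on counts per 10000, log transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (seed 0), which gave 26 clusters. Clusters were named from 22 marker lists, a marker counting as detected in at least 10% of a cluster's cells and at 2 times its level elsewhere. Classes carry the ending -like because no reference cells were present. The named classes were hair cells, supporting cells, interdental or inner sulcus cells, Schwann or satellite glia, neurons, fibroblasts, endothelial cells, macrophages and osteoblasts, and the other marker lists named no cluster. The hair cell list held 17 genes. A leading gene was detected in at least 25% of a cluster's cells and ranked with a pseudocount of 10 CPM.

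Expression was summed over the cells of a library, or of a class with at least 50 kept cells in each library, and scaled to UMIs per 1000000 UMIs (CPM). Ratios of cocktail over vehicle are log2 values with the exact conditional counting interval at 95%. Shares of cells have Clopper-Pearson intervals, and differences of shares have Newcombe intervals. Ratios of Atoh1 levels or shares between groups of cells have log (Katz) intervals or intervals from 2000 resamplings of cells, which describe these 2 libraries alone. With 1 library per group no p-value was computed and cells were not treated as replicates. Against a count of 0 a ratio was bounded with a floor of 3 counts per library. For medians, and for single genes under the alternatives, a prior of 0.5 count was added to each library. The 26 response lists were summarised by the median over members with at least 20 UMIs, placed among 10000 random lists matched in 10 bins of expression. In all, 3 list genes were not in the files. Hair cell markers and cell cycle genes were counted per cell after thinning to 1053 UMIs, the depth of the 10th percentile of kept cells, and again at the median of 11318 UMIs. Cells below the depth in use were left out. A cell counted as cycling with at least 2 UMIs of 7 genes.

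The classes, lists, filters and the rule for naming genes were fixed in advance. By that rule genes with at least 50 UMIs were ranked by the bound of the counting interval nearest 0, without mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed model genes. The first 8 higher and 8 lower were named in the whole library, 10 and 10 in interdental- or inner-sulcus-like cells, which replaced the supporting-cell-like cells because fewer than 50 of those were kept, and 5 and 5 in each other class or cluster. Up to 2 genes per list and direction were added in the whole library and in that class, and Atoh1, Puf60, Mxi1, Sox2, Myc and the hair cell markers were always listed. A gene that the rule gave, and some markers, are not reported here, and the counts of genes given by the rule include it. FIR was taken as the FBP-interacting repressor, encoded by Puf60. The same rank without each gene's highest cell was added after the data were seen. List members given for other classes and clusters were also chosen by the rank after the data were seen. Groups of clusters were defined after the clustering: 4 Gal- and Cck-high clusters with at least 5000 CPM of Gal and 2000 CPM of Cck, and 15 clusters with at least 300 CPM of Epcam. A gene was called outlying in a cell when it took at least 1% of the cell's UMIs and at least 20 times its share in the cell with the third highest share.

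The ratio step was tested on simulated data made from the whole library, with 23776 genes in the step. For 50 genes each, changes of 1, -1, 2 and -2 on the log2 scale gave median estimates of 1.00, -1.00, 1.98 and -2.02, and the intervals covered the made change for 100%, 98%, 96% and 100% of them. For 11987 unchanged genes the intervals covered 0 in 94.5%. A list of 15 raised genes had a median of 1.01 at percentile 100, and 5.5% of 200 unchanged lists fell in the outer 5%. The simulation holds counting error only.

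Alternatives changed 1 choice at a time: no cell filter, at least 1000 UMIs per cell, at most 10% mitochondrial UMIs, called doublets kept, Leiden resolution 0.5 or 2.0, 4000 variable genes, CPM without mitochondrial and ribosomal genes, median-ratio scaling, mean of per-cell CPM, cell classes weighted alike, a prior of 3 counts, list members with at least 100 UMIs or with no minimum, other depths of thinning and other minimum counts of cell cycle UMIs. Added after the data were seen were cells with at least 5000 UMIs, the share among Epcam-expressing clusters, clustering without the 10 leading genes of every cluster, leaving out clusters 5 and 17, leaving out each gene's highest cell, class weighting for the lists and target genes, and the deeper thinning for cell cycle genes. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.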

Results

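Single-cell RNA of adult mouse cochlear sensory epithelium was measured in 2 droplet libraries, 1 per condition. Whole cochlear explants of C57BL/6J mice aged 4 to 6 weeks were held for 4 days in a reprogramming cocktail or in vehicle, and both groups were then given an adenovirus carrying Atoh1 (ad.Atoh1) for 2 weeks. The cocktail held valproic acid (a histone deacetylase inhibitor, 1.5 mM), lithium chloride (an inhibitor of GSK3 that raises Wnt signalling, 8 mM), forskolin (an activator of adenylyl cyclase, 20 µM) and siRNAs named FIR and Mxi1 (0.02 µM each). By the labels 5 cultures per group were captured together. Cells were not assigned to cultures here, so the difference between the libraries has no replicate check, no test of condition was possible, and each value is given per library. Intervals are 95% and cover counting error only. Libraries are named by their labels throughout.

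The cocktail library held 1403 barcodes with 19625208 UMIs (unique transcript molecules), and the vehicle library held 1688 barcodes with 23108868 UMIs, against about 1400 and about 1700 cells stated by the submitters. After filtering, 1329 cocktail and 1582 vehicle cells were kept. Their median depths were 10391 and 12267 UMIs per cell, with quartiles of 2166 and 23570 UMIs in the cocktail library and 4668 and 21752 UMIs in the vehicle library. The cocktail library therefore held more shallow cells. A count of 3 UMIs, the limit that a count of 0 allows, corresponded to 0.154 CPM (UMIs per 1000000 UMIs of the library) in the cocktail library and 0.131 CPM in the vehicle library.

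The first comparison asked whether the delivered gene and the siRNA target genes differed between the libraries. Atoh1, the transcription factor that starts hair cell differentiation, was higher in the cocktail library. Puf60, which encodes the Myc repressor FIR and was taken as the target of the FIR siRNA, was alike in both libraries. Mxi1, which encodes an antagonist of Myc, was lower in the cocktail library, largely through 1 vehicle cell. Sox2, a factor of the prosensory epithelium and of glia, was also lower. The siRNAs were given before the 2 weeks of ad.Atoh1, so the levels of Puf60 and Mxi1 at collection do not check the labels, and vector and endogenous Atoh1 transcripts were not distinguished in the counts.

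Atoh1 (ENSMUSG00000073043, GRCm38 chromosome 6, 64729125 to 64731245, plus strand) stood at 74.0 CPM (Poisson interval 70.3 to 78.0, 1446 UMIs) in the cocktail library and 47.7 CPM (45.0 to 50.7, 1097 UMIs) in the vehicle library, a log2 ratio of 0.63 (0.52 to 0.75). Cells with an Atoh1 UMI made up 21.6% of the cocktail and 20.1% of the vehicle library. In interdental- or inner-sulcus-like cells, which served as background for Atoh1, 1.49% of 202 cocktail cells and 0 of 136 vehicle cells had an Atoh1 UMI, at median depths of 12666 and 8087 UMIs. Atoh1 was most abundant in cluster 5, at 632 CPM in the cocktail and 525 CPM in the vehicle library. Without clusters 5 and 17, left out after the data were seen, the Atoh1 log2 ratio was 0.35 (0.19 to 0.51), and as a mean of per-cell CPM it was 0.38. Puf60 (ENSMUSG00000002524, chromosome 15, 76070182 to 76080924, minus strand) stood at 59.9 and 59.3 CPM, a log2 ratio of 0.01 (-0.10 to 0.13), which became 0.15 as a mean of per-cell CPM. Within cluster 1, Puf60 was higher in the cocktail library, at 1.16 (0.43 to 1.94). Mxi1 (ENSMUSG00000025025, chromosome 19, 53310518 to 53375810, plus strand) stood at 53.5 and 106 CPM, a log2 ratio of -0.98 (-1.09 to -0.88). One vehicle cell of cluster 5 held 911 of the 2426 vehicle UMIs of Mxi1, and without the highest cell of each library the ratio was -0.34 (-0.46 to -0.22). In fibroblast-like cells Mxi1 was at -0.48 (-0.90 to -0.07), and in cluster 3 it was at -0.21 (-0.44 to 0.03). Sox2 stood at 13.1 and 28.1 CPM, a log2 ratio of -1.11 (-1.32 to -0.90). Sox2 was lower within interdental- or inner-sulcus-like cells at -1.07 (-1.79 to -0.35) and within cluster 3 at -0.76 (-1.28 to -0.25). Myc stood at 13.8 and 11.4 CPM, a log2 ratio of 0.28 (0.03 to 0.53).

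**Figure D1:**
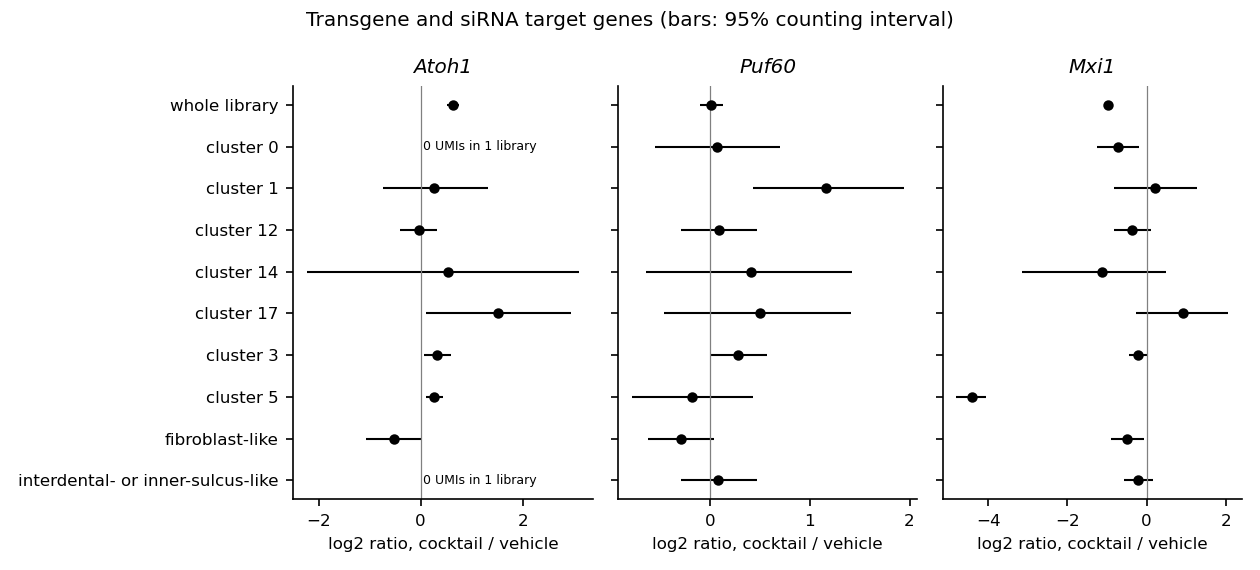
Log2 ratio of CPM, cocktail over vehicle (horizontal axis), of Atoh1, Puf60 and Mxi1 in the whole library and in each class or cluster with at least 50 cells per library; points are ratios, bars are 95% counting intervals, and Atoh1 has no point where 1 library held 0 UMIs. In the whole library Atoh1 lies at 0.63, Puf60 at 0.01 and Mxi1 at -0.98.

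The second comparison asked which cell types each library contained, given the stated purpose of regenerating hair cells. Hair-cell-like cells (cluster 18 alone) and supporting-cell-like, glia-like, osteoblast-like and endothelial-like cells made up smaller shares of the cocktail library. Larger shares of it fell to epithelial clusters rich in the neuropeptide transcripts Gal and Cck and to cells resembling the interdental or inner sulcus epithelium, which makes tectorial membrane proteins. The clusters rich in Gal and Cck also carried some hair cell genes. The share of hair-cell-like cells is therefore not that of all cells with such genes. Neuron-like and macrophage-like cells were few in both libraries. Shares depend on what each dissection carried over, and the cocktail cells were shallower.

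Hair-cell-like cells (cluster 18, led by Ptprq, Cabp2, Espn and Loxhd1) numbered 9 in the cocktail and 37 in the vehicle library. Their shares were 0.677% (Clopper-Pearson 0.310 to 1.28) and 2.34% (1.65 to 3.21), a difference of -1.66 points (Newcombe -2.59 to -0.783). Supporting-cell-like cells (cluster 23) numbered 1 and 22, a difference of -1.32 points (-2.02 to -0.729). The leading genes of cluster 23 held markers of the supporting cell list (Slc1a3 and Otog) and of the interdental list (Otogl and Otog). The unnamed cluster 8, led in part by the supporting cell marker Epyc, held 30 and 33 cells. Glia-like cells numbered 30 and 169, at 2.26% and 10.7%. Of these, cluster 24 held 2 cocktail and 52 vehicle cells. Osteoblast-like cells numbered 1 and 53. Endothelial-like cells numbered 0 of 1329, which by a limit of 3 counts allows a share of up to 0.226% (Clopper-Pearson upper bound 0.277%), and 25 of 1582, or 1.58%. Supporting-cell-like, osteoblast-like and endothelial-like cells and cluster 24 came almost wholly from the vehicle library, so class and library are not separable there. The 4 Gal- and Cck-high clusters (1, 3, 19 and 20) together held 453 cocktail cells and 325 vehicle cells, at 34.1% (31.5 to 36.7) and 20.5% (18.6 to 22.6). Their difference was 13.5 points (10.3 to 16.8), made up mainly of cluster 1 at 7.84 points (5.56 to 10.2) and cluster 3 at 5.27 points (2.93 to 7.66). Cells of cluster 1 were shallow, at a median of 1813.5 UMIs, whereas those of cluster 3 had 23345 UMIs. Interdental- or inner-sulcus-like cells, led by Ceacam16 and Clu, numbered 202 and 136, at 15.2% and 8.60%. Fibroblast-like cells numbered 194 and 164, a difference of 4.23 points (1.83 to 6.68). Of these, cluster 9 held 80 cocktail and 11 vehicle cells at a median of 1013 UMIs, and among cells with at least 5000 UMIs the difference was 0.790 points (-2.17 to 3.85). Cluster 12, led by Opcml, Mfap4 and the myoblast fusion gene Mymk, held 59 and 120 cells, a difference of -3.15 points (-4.86 to -1.41). Cluster 10, led by Vmo1, Chil1 and Tecta, held 24 and 80 cells. Neuron-like cells numbered 5 and 15 and macrophage-like cells 7 and 5, and the intervals of both differences held 0.

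**Figure D2:**
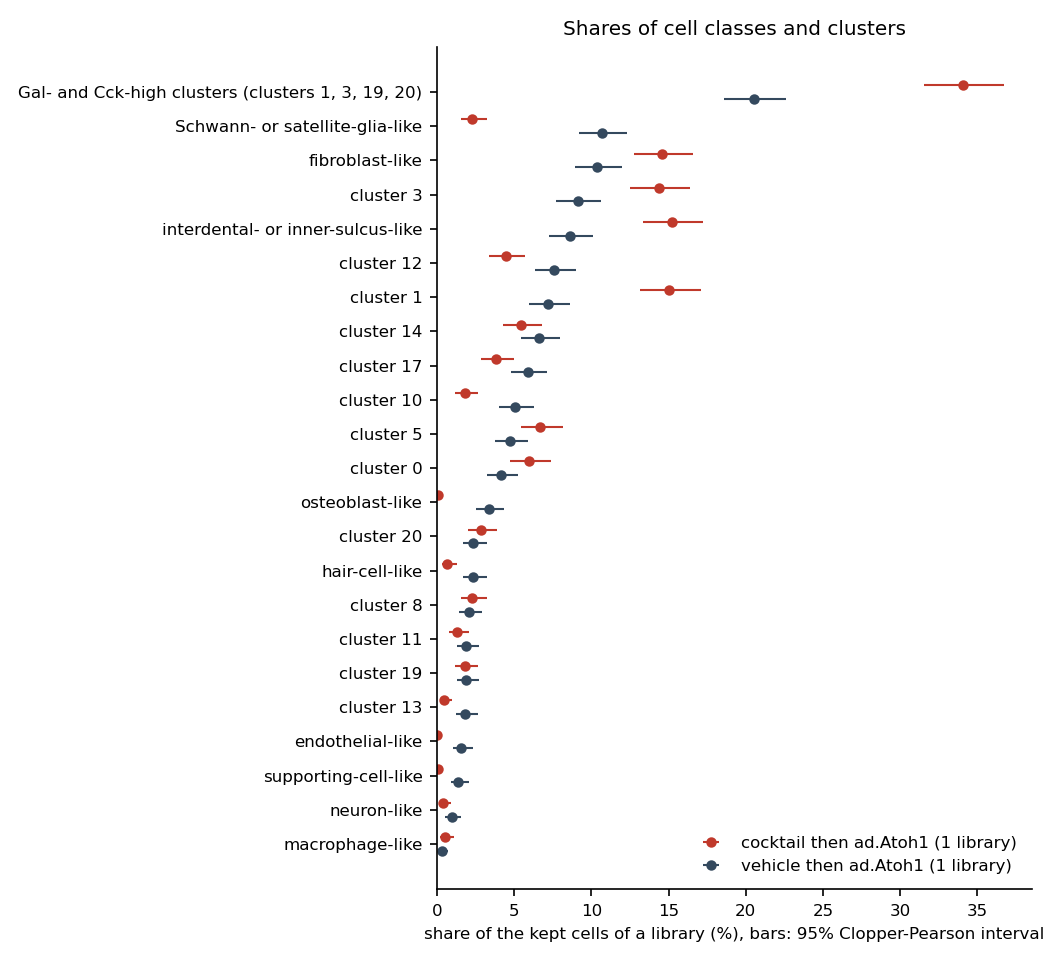
Share of kept cells in percent (horizontal axis) of each named class and unnamed cluster in the cocktail and vehicle libraries; points are shares and bars are 95% Clopper-Pearson intervals. Gal- and Cck-high clusters hold 34.1% of cocktail and 20.5% of vehicle cells, and glia-like cells 2.26% and 10.7%.

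The third comparison asked how far hair cell genes were expressed, and in which cells. Espn, which bundles actin in stereocilia, Pou4f3 and Gfi1, the transcription factors that maintain hair cells, and Otof, needed for release at their synapse, were all lower in the cocktail library. Pvalb, a calcium buffer of hair cells that the Gal- and Cck-high clusters also carried, was higher. Those clusters expressed Atoh1, its target Hes6, Pvalb, Cib2 and Lhx3, with little of Pou4f3 or of the transduction channel gene Tmc1. Most hair cell genes came from few cells, so the share of hair-cell-like cells moves their library totals.

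Espn stood at 31.6 CPM in the cocktail and 78.2 CPM in the vehicle library, a log2 ratio of -1.30 (-1.44 to -1.17). Pou4f3 was at -0.67 (-1.08 to -0.28), Gfi1 at -0.96 (-1.45 to -0.49), Otof at -0.54 (-0.71 to -0.36) and Myo7a at -0.68 (-1.07 to -0.30). Pvalb was at 0.41 (0.36 to 0.46), with 329 and 248 CPM. Lhx3 and Chrna9 had intervals that held 0. The prestin gene Slc26a5 had 2 and 5 UMIs and Ocm had 1 and 3, too few to compare. Over both libraries Pou4f3 stood at 256 CPM in hair-cell-like cells and at 6.91 CPM in cluster 3, and Tmc1 stood at 412 and 0.880 CPM. Espn stood at 2083 and 44.7 CPM in the same cells, whereas Pvalb stood at 960 and 772 CPM. Hes6 was at 72.4 CPM in hair-cell-like cells and at 575 CPM in cluster 3, where 56.1% of cells had an Atoh1 UMI. Otof reached 317 CPM in cluster 19.

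Thinning to 1053 UMIs left out shallower cells and kept 1141 of 1329 cocktail and 1479 of 1582 vehicle cells. Thinning to 11318 UMIs kept 632 and 824. At 1053 UMIs, 25 of 1141 cocktail cells (2.19%, 1.42 to 3.22) and 47 of 1479 vehicle cells (3.18%, 2.34 to 4.20) had UMIs of at least 3 of the 17 hair cell markers, a difference of -0.987 points (-2.23 to 0.300). The interval held 0, and without thinning the difference was 0.311 points (-2.71 to 3.36) and at 11318 UMIs it was 2.84 points (-1.61 to 7.36), so no difference in this share was detectable. This share joins hair-cell-like cells, a smaller share of the cocktail library, with Gal- and Cck-high cells, a larger one. It therefore follows neither group alone. Among hair-cell-like cells 8 of 9 and 28 of 36 met this count, and among Gal- and Cck-high cells 4.61% and 5.88% did. Macrophage-like cells, taken as background at the same thinned depth, gave 0 of 4 and 0 of 5, and fibroblast-like cells gave 0 of 149 and 1 of 157. At 11318 UMIs per cell, 60.3% of cocktail and 65.9% of vehicle cells in the Gal- and Cck-high clusters had at least 3 of the markers, against 0 of 102 and 1 of 130 fibroblast-like cells.

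**Figure D3:**
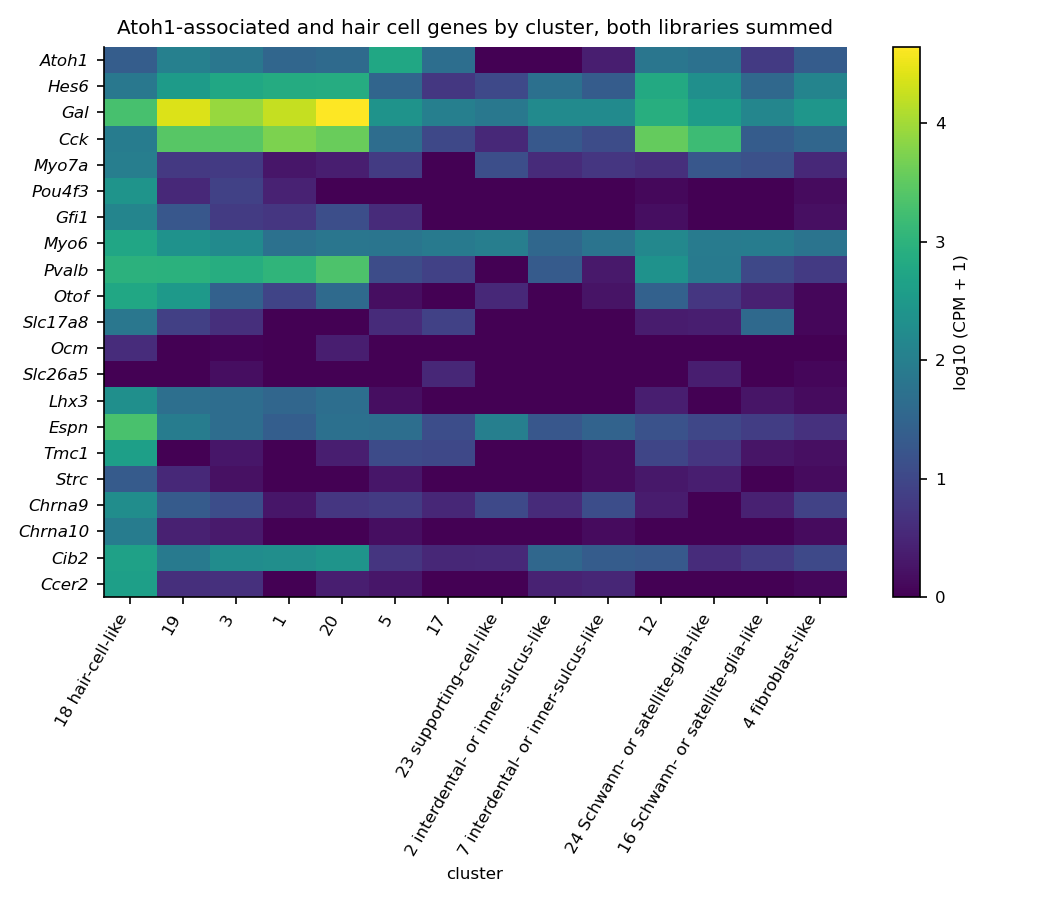
Level of Atoh1, Hes6, Gal, Cck and the 17 hair cell markers (vertical axis) in selected clusters (horizontal axis), as the colour of log10 of CPM plus 1 with both libraries summed and no error shown. Espn stands at 2083 CPM in hair-cell-like cells and 44.7 CPM in cluster 3, whereas Pvalb stands at 960 and 772 CPM.

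The fourth comparison took all transcripts of each library together. Genes of the cell types that were scarce in the cocktail library led the lower side, among them Ifitm5 and Alpl of mineralising osteoblasts and Cldn5, Adgrl4 and Esam of endothelial cells. On the higher side stood C1qa, a complement gene of macrophages, and other genes that 1 cell mostly supplied. C1qa was a leading gene of the macrophage-like cells, which numbered only 7 in the cocktail and 5 in the vehicle library. Ccl5 and Cxcl10, chemokines induced by interferon, were higher without resting on 1 cell. These sums move with the shares of the cell types.

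Ifitm5 had 12 cocktail and 1728 vehicle UMIs, a log2 ratio of -6.94 (-7.89 to -6.13). Alpl had 38 and 1364 UMIs, at -4.93 (-5.44 to -4.47). Cldn5 had 0 and 119 UMIs, and against the floor of 3 counts per library its log2 ratio was at most -5.08. Adgrl4 was at -6.30 and Esam at -5.52, each with 3 cocktail UMIs. When the cell classes were weighted alike in both libraries, which leaves out the endothelial-like cells, Adgrl4 was at 1.29. C1qa had 412 and 4 UMIs, at 6.92 (5.55 to 8.80), with 244 of the cocktail UMIs in 1 cell, and stood at 6.04 without the highest cells. Other genes of the naming rule were Fcgr4, Hsd17b3, Il12rb1, Tmbim7, Has1 and Krtap15 on the higher side and Prokr2, Faddos and Adamts16 on the lower side. For 11 of the 16 genes that the rule gave, 1 cell held at least 50% of the UMIs. Fcgr4, for example, had 551 cocktail UMIs of which 548 were in 1 cell, and its log2 ratio of 7.76 became 0.82 without the highest cells. Hsd17b3, Il12rb1 and Tmbim7 stood at -1.81, -0.049 and -0.10 without clusters 5 and 17, and Adamts16 at 0.88, with 0.5 count added per library. Krtap15 had all of its 66 UMIs in 1 cocktail cell. Ranking without each gene's highest cell, chosen after the values were seen, added C1qc at 4.35 and Ccl5 at 2.95 (2.81 to 3.09) on the higher side and the bone sialoprotein gene Ibsp at -4.07 on the lower.

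**Figure D4:**
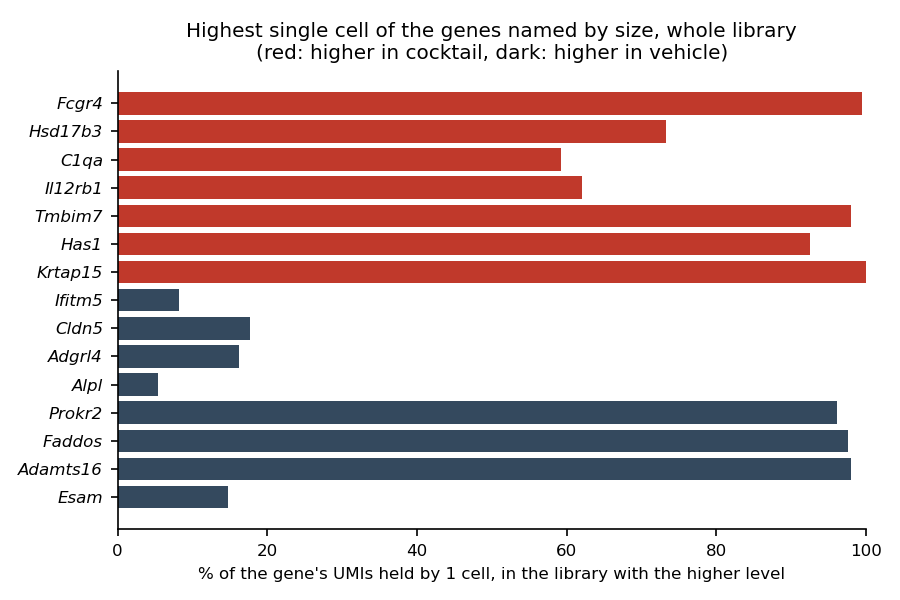
Percent of a gene's UMIs held by 1 cell (horizontal axis), in the library with the higher level, for genes of the naming rule in the whole library; bars are red for genes higher in the cocktail library and dark for genes higher in the vehicle library. Krtap15 had all of its 66 UMIs in 1 cell, and Fcgr4 had 548 of 551.

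Fixed gene lists were then compared over the whole library. Genes induced by interferon, inflammatory chemokines, and enzymes of cholesterol synthesis were higher in the cocktail library. Hair bundle genes, fibrillar collagens, cell cycle genes, p53 targets and genes of hypoxia and glycolysis were lower. The lists tied to the cocktail's own agents, Wnt targets for lithium and cAMP targets for forskolin, had medians near 0, and the list for valproic acid, genes induced by deacetylase inhibitors, leaned lower. The cocktail was given before the 2 weeks of ad.Atoh1, so levels at collection do not show whether its agents acted on these genes. A percentile among 10000 random lists of matched expression describes these 2 libraries and tests nothing.

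All 15 interferon response genes were higher in the cocktail library, with a median log2 ratio of 0.83 (percentile 100), and Cxcl10 was at 269 and 39.3 CPM, a log2 ratio of 2.78 (2.67 to 2.88). Of 12 inflammatory genes 9 were higher, with a median of 0.94 (percentile 100). Among them the monocyte attractant Ccl2 was at 1.57 (1.50 to 1.64), whereas the neutrophil attractant Cxcl2 was at -0.92 and the iron-binding Lcn2 at -0.46. Cholesterol synthesis had 13 of 14 genes higher and a median of 0.22 (percentile 99.95), with Fdft1 at 0.50 and Insig1 at 0.45. The epithelial junction list was at 0.23, with the adhesion gene Cdh1 at 0.77. In that list Tjp1 was at 1.70 with 3480 of its 4948 cocktail UMIs in 1 cell. Antioxidant genes were at 0.18, Mt2 among them at 0.35. Of 23 hair bundle genes 19 were lower, with a median of -0.81, and Ptprq, a phosphatase of the bundle, was at -1.96 (-2.15 to -1.77). That median was 0.10 when classes with at least 50 cells per library were weighted alike, which leaves the hair-cell-like cells out. Hair cell transcription genes had a median of -0.38 with the calcium-binding Calb2 at -2.08, and synapse genes a median of -0.25. Otic progenitor genes were at -0.39, with Hmx2 at -2.20, but at 0.05 as a mean of per-cell CPM. Fibrillar matrix genes were at -0.44, with Col1a1 at -2.37 (-2.48 to -2.26) and Postn at -1.88, against Dcn at 0.67. Col1a1 was a leading gene of the osteoblast-like cluster 22, which held 1 cocktail and 53 vehicle cells, so its sum moves with that share. Cell cycle genes were at -0.29, hypoxia and glycolysis genes at -0.32 with Car9 at -1.19, p53 targets at -0.25 with Cdkn1a at -0.59, and genes of the epithelial to mesenchymal transition at -0.27 with Vim at -0.75. The remaining medians were -0.04 for Wnt targets, -0.06 for cAMP and CREB targets, 0.11 for the Notch pathway, 0.03 for Myc and its partners, -0.04 for Myc targets, -0.13 for genes induced by deacetylase inhibitors (6 of 7 lower, percentile 3.77), 0.08 for supporting cell identity, 0.08 for immediate early genes, -0.06 for TGF beta response, 0.05 for matrix proteases, -0.10 for the integrated stress response and 0.05 for sex linked genes. Within those lists Clu, a chaperone that also leads the interdental- or inner-sulcus-like cells, was the 1 of 7 genes induced by deacetylase inhibitors that was higher, at 0.84 (8870 and 4948 CPM), with Cdkn1a and Txnip (-0.24) lower. The Notch target Nrarp was at 0.80 and the phosphodiesterase Pde4b at 0.58, while the supporting cell gene Tectb had 2 and 52 UMIs.

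**Figure D5:**
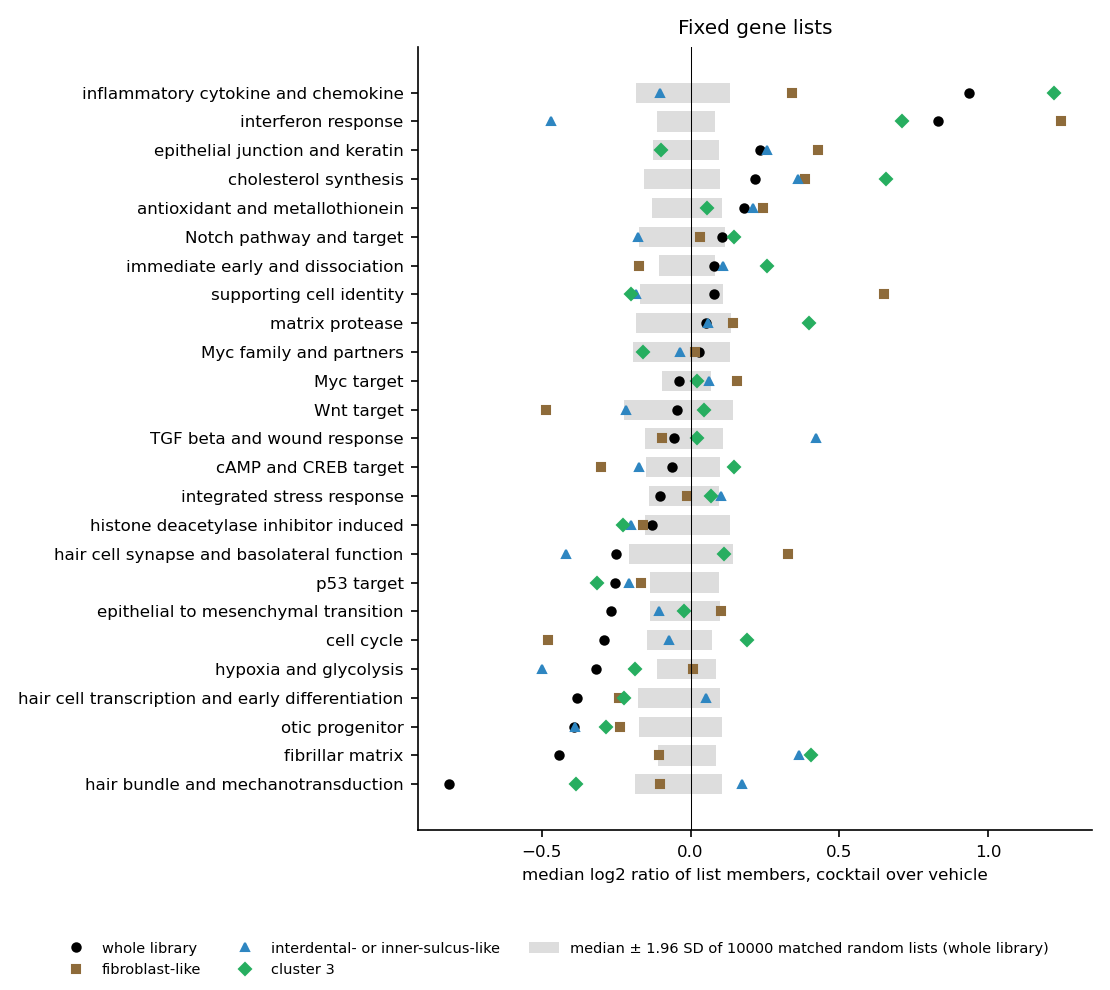
Median log2 ratio, cocktail over vehicle (horizontal axis), of the members of each fixed gene list except the sex linked list; symbols are the whole library, fibroblast-like cells, interdental- or inner-sulcus-like cells and cluster 3, and grey bars span 95% of matched random lists in the whole library by a normal approximation. The interferon response lies at 0.83 in the whole library, at 1.25 in fibroblast-like cells and at -0.47 in interdental- or inner-sulcus-like cells.

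Within the interdental- or inner-sulcus-like cells, the epithelial class with the most cells, the comparison asked how this epithelium differed between the libraries. The S100 family gene S100a6, found in dividing and injured epithelia, the otolith and tectorial matrix genes Otol1 and Otogl, and the prosensory factors Sox2 and Gata3 were lower in the cocktail library. Higher were Lgals1, which encodes a secreted galectin, the cyclin gene Ccnd1, the tight junction gene Cldn4, the keratin gene Krt8 and the protease inhibitor gene Timp1. Interferon and glycolysis genes were lower, against the direction of the interferon genes in other cells. Cocktail cells of this class were deeper, with medians of 12666 against 8087 UMIs. Otol1, Otogl and Ptgds also lead clusters 23 and 13, which were mostly vehicle cells, and free RNA was not removed from the counts.

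S100a6 had 55 and 781 UMIs, a log2 ratio of -4.90 (-5.32 to -4.50), with 534 of the vehicle UMIs in 1 cell and -3.63 without the highest cells, and Otol1 was at -3.45 and Otogl at -2.48. Lgals1 had 571 and 81 UMIs, at 1.75 (1.41 to 2.10). Gata3 was at -1.07 (-1.42 to -0.72), Cd44 at -1.51 and Ccnd1 at 0.98 (0.68 to 1.30). Of 14 interferon genes 3 were higher, with a median of -0.47 (percentile 0.01), or -0.17 as a mean of per-cell CPM, Ifit1 at -1.13 (-1.35 to -0.90) and Ifi27l2a at 0.50. Hypoxia and glycolysis genes had a median of -0.50, with Tpi1 at -0.75 and Gapdh at -0.64. Epithelial junction genes had a median of 0.26, Cldn4 at 0.96 and Krt8 at 0.59, and cholesterol synthesis genes had a median of 0.36. Timp1 was at 0.94 (0.78 to 1.10). Of the 20 genes of the naming rule 7 had at least 50% of their UMIs in 1 cell, and Cep85, Cep57l1, Rgs20, Stc1 and Nwd1 had the opposite sign under at least 1 alternative. The others of the rule were Mt3, Gk5, Prss22, Serpinb1a and Wdr34 on the higher side and Pclo, Ptgds, Car14, Scd1, S100b and Nckap5 on the lower.

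Cluster 3, the deep Gal- and Cck-high cluster, was compared to ask how epithelial cells that carried Atoh1 differed. Some genes of hair cell and sensory identity, Lhx3, Barhl1, Pax2 and Espn, were lower in the cocktail library, as were the simple keratins Krt7 and Krt18 and the neuropeptide gene Npy. The Atoh1 target Hes6 and some genes of the Notch list (Hes1, Nrarp and the ligand gene Dll1) were higher, while others of that list were lower. Hes6 and Dll1 share with Lhx3 and Barhl1 the list of hair cell transcription and early differentiation, so members of that list went both ways. Also higher were interferon genes, sterol enzyme genes and Lcn2 of the inflammatory list. Clu and Ceacam16, abundant in the interdental-like cells, were higher here too. Free RNA from those cells was not removed from the counts.

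Lhx3 was at -0.90 (-1.21 to -0.59), Barhl1 at -1.20, Pax2 at -1.21 (-1.65 to -0.78) and Espn at -0.45 (-0.75 to -0.14). Krt7 was at -2.12 (-2.33 to -1.92) and Krt18 at -0.85. Hes6 was at 0.33 (0.25 to 0.42), Dll1 at 0.66, Hes1 at 0.43 and Nrarp at 0.85. Of 12 Notch genes 7 were higher and 5 lower, with a median of 0.14 (percentile 95.4). All 14 cholesterol synthesis genes were higher, with a median of 0.66 (percentile 100) and Idi1 at 1.23 (0.82 to 1.67). The interferon response had 13 of 15 genes higher, with a median of 0.71, or 1.01 without each gene's highest cell. Ifi27l2a was at 2.50 (2.23 to 2.79) and Lcn2 at 2.06 (1.85 to 2.27). Hair bundle genes had a median of -0.39 and p53 targets one of -0.31. Myc was at -0.97 (-1.68 to -0.26), and without the highest cells its ratio was -0.50 with an interval that held 0. The naming rule gave Slamf1, Runx2, Xlr5a, Flt3 and Kcnip4 on the higher side and Mrap, Ccdc63, Anxa1, Efcab5 and Krt17 on the lower, and 9 of these 10 had at least 50% of their UMIs in 1 cell. Named after the values were seen, with the highest cells left out, Ceacam16 was at 3.27 and Npy at -2.59 (-2.75 to -2.43).

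Fibroblast-like cells were compared to ask how the mesenchyme differed. Interferon-induced genes and the chemokines Cxcl10, Ccl5, Ccl2 and Ccl7, which draw lymphocytes and monocytes, were higher in the cocktail library. Mitotic genes such as Cenpf and Ube2c were lower, as was Postn, a matrix protein of wounded tissue, whereas the small proteoglycan gene Dcn was higher. Myc was higher here. The class joins clusters 4, 6 and 9, which the libraries shared unevenly.

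Cxcl10 had 4928 and 695 UMIs, a log2 ratio of 2.72 (2.61 to 2.84), Ccl5 was at 2.61 and Rsad2 at 2.54. All 15 interferon genes were higher, with a median of 1.25 (percentile 100). Ccl2 was at 1.61 (1.52 to 1.69) and Ccl7 at 1.40, whereas Cxcl2 was at -1.90. Of 25 cell cycle genes 20 were lower, with a median of -0.48, Cenpf at -0.94 and Ube2c at -0.86. Postn was at -2.42 (-3.07 to -1.83) and Dcn at 0.48. Wnt targets had a median of -0.49, Myc targets one of 0.16, and Myc itself was at 0.89 (0.44 to 1.34). The naming rule gave Atp12a, Dscam, Serpinb5 and Epyc among those on the higher side, all with 0 vehicle UMIs, and Npy, Rasef, Mymk, Dnah10 and Myh11 on the lower, and 9 of the 10 that it gave had at least 50% of their UMIs in 1 cell.

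In the smaller clusters interferon genes were again higher in the cocktail library in clusters 0, 1 and 12. Cluster 0, which shared fibrocyte and tympanic border markers, had more of Lcn2, Clu and the immediate early genes that dissociation induces, and less of every fibrillar matrix gene. In cluster 1 the cell cycle inhibitor gene Cdkn1c and the epithelial gene S100a6 were lower. Cluster 12 had less of the collagen genes Col3a1 and Col1a2. Free RNA was not removed here either, and cells rich in collagen or Clu differed in number between the libraries. Clusters 5 and 17 gave no gene of the naming rule that was spread over many cells.

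Interferon medians were 1.02 in cluster 0, 0.57 in cluster 1 and 1.33 in cluster 12, where Isg15 was at 1.58 (1.39 to 1.76). In cluster 0 Lcn2 was at 3.29 (3.08 to 3.49), Clu at 2.95 (2.77 to 3.14) and G0s2 at -4.38, and the 14 fibrillar matrix genes had a median of -1.28. Immediate early and dissociation genes were higher there in 13 of 14, with a median of 0.65 (percentile 100), against -0.26 in cluster 1, -0.28 in cluster 12 and -0.51 in cluster 14. In cluster 1 S100a6 was at -3.56 (-4.00 to -3.13), Cdkn1c at -1.62 (-1.80 to -1.44) and Ifitm3 at 1.74 (1.41 to 2.07), at median depths of 1429.5 and 2490.5 UMIs. In cluster 12 Col3a1 was at -3.06 and Col1a2 at -1.99 (-2.39 to -1.60), and 12 of 13 integrated stress response genes were higher, with a median of 0.34. In cluster 14 Chil1 was at 1.32 and Nupr1 at 1.30, and Cdkn1c at -2.56. In clusters 5 and 17 each of the 10 named genes had at least 50% of its UMIs in 1 cell, among them Mme with 5020 of 5033 cocktail UMIs in cluster 5.

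The last comparison asked whether cells with mitotic transcripts differed in number. At the main depth and minimum count they were a smaller share of the fibroblast-like cells in the cocktail library, but other settings narrowed or turned this difference. Cluster 6 of that class, led by Top2a and Mki67, held 19 cocktail and 40 vehicle cells. Cluster 11, an Epcam-expressing cluster led by Ube2c, Cenpf and Top2a, held 17 cocktail and 30 vehicle cells. With fewer than 20 cocktail cells it was given no share of cycling cells of its own. Interdental- or inner-sulcus-like cells and cluster 3, the large epithelial groups, gave none in either library at the main depth. Cells thinned to 1053 UMIs keep few mitotic transcripts, and the differences in the whole library and among fibroblast-like cells varied with depth and with the minimum count of UMIs. Cells below 1053 UMIs were left out, which kept 149 of 194 cocktail and 157 of 164 vehicle fibroblast-like cells.

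With at least 2 UMIs among Mki67, Top2a, Ccnb1, Cdk1, Birc5, Ube2c and Cenpf, 23 of 1141 cocktail cells (2.02%, 1.28 to 3.01) and 51 of 1479 vehicle cells (3.45%, 2.58 to 4.51) were counted, a difference of -1.43 points (-2.68 to -0.149). That difference was -0.0504 points (-1.82 to 1.79) with at least 1 UMI and -1.30 points (-2.17 to -0.461) with at least 4, and with at least 2 UMIs it was -1.46 points (-3.53 to 0.649) without thinning and -2.67 points (-5.75 to 0.514) at 11318 UMIs, so it was not detectable under every setting. Among fibroblast-like cells 10 of 149 (6.71%, 3.27 to 12) and 28 of 157 (17.8%, 12.2 to 24.7) were counted, a difference of -11.1 points (-18.5 to -3.77). With at least 1 UMI the fibroblast-like difference was -3.23 points (-12.9 to 6.59) at 1053 UMIs, 6.37 points (-6.48 to 19) at 11318 UMIs and 1.92 points (-8.39 to 12.2) without thinning. With at least 2 UMIs it was -4.34 points (-14.0 to 5.32) without thinning, and among cells with at least 11318 UMIs, a depth added after the data were seen, it was -0.437 points (-12.7 to 12) at 37.3% and 37.7%. With at least 4 UMIs it was -5.66 points (-10.9 to -1.08) at 1053 UMIs, -5.20 points (-16.9 to 6.95) at 11318 UMIs and -9.54 points (-18.7 to -0.357) without thinning. The background in interdental- or inner-sulcus-like cells was 0 of 185 and 0 of 124, and in cluster 3 it was 0 of 191 and 0 of 144. At 11318 UMIs cluster 3 gave 4 of 170 and 3 of 125 cells, and interdental- or inner-sulcus-like cells gave 0 of 106 and 2 of 47. The Epcam-expressing cluster 10 gave 3 of 22 and 5 of 59 at that depth.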

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

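The tests named here were chosen after the results were seen, except the test of neighbouring genes in the third pattern. With 1 library per condition the differences between cell groups listed first were not tested.

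Several values had opposite directions in cell groups under the same comparison of cocktail with vehicle. The interferon response list had a median log2 ratio of 0.71 in cluster 3 and 1.25 in fibroblast-like cells, but -0.47 in interdental- or inner-sulcus-like cells, or -0.17 there as a mean of per-cell CPM. The immediate early and dissociation list stood at 0.26 in cluster 3 and -0.17 in fibroblast-like cells. The supporting cell identity list stood at -0.20 in cluster 3 and 0.65 in fibroblast-like cells, but at -0.22 in the latter with no minimum beyond 1 UMI, so that contrast depends on the members counted. Espn stood at -0.45 in cluster 3 and 0.74 in interdental- or inner-sulcus-like cells, and Myc at -0.97 in cluster 3 and 0.89 in fibroblast-like cells. Without the highest cells Myc in cluster 3 was at -0.50 with an interval that held 0. Members of each list went both ways in each of these groups, except that all 15 interferon genes were higher in fibroblast-like cells.

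The first pattern weighed was the smaller share of hair-cell-like cells, cluster 18 alone, in the cocktail library. It does not cover the Gal- and Cck-high clusters, which carried some hair cell genes and were a larger share there. Dilution by cells of other tissues would need more of those in the cocktail library, yet Epcam-expressing clusters were the larger share there, by 10.8 points (7.35 to 14.2). If shallower cells had hidden them, it would have closed among cells with at least 5000 UMIs, yet it was -1.87 points (-3.02 to -0.720). What stays open is that tissue kept in dissection or surviving dissociation differed, since 3 of the 6 named classes outside the cochlear epithelium (osteoblast-like, endothelial-like and glia-like) were also lower. Fibroblast-like cells were higher by 4.23 points (1.83 to 6.68), but by 0.790 points (-2.17 to 3.85) among cells with at least 5000 UMIs. The intervals of neuron-like and macrophage-like cells held 0. With 1 library per condition a difference in tissue cannot be told apart from an effect of the cocktail.

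The second pattern was the larger share of the Gal- and Cck-high clusters in the cocktail library. Shallow cells of cluster 1, or fewer cells of other tissues, would account for it only if the difference vanished among cells with at least 5000 UMIs, where it was 12 points (8.13 to 15.9), or among Epcam-expressing clusters, where it was 13.8 points (9.43 to 18.1). A matching excess of cells with an Atoh1 UMI was not seen among cells with at least 5000 UMIs. There the ratio of the shares with an Atoh1 UMI was 1.12 (0.902 to 1.40), against 1.63 for these clusters. Their quotient was 0.690 (0.530 to 0.895 over resampled cells). The share with an Atoh1 UMI rose with depth, so it undercounts cells that carry Atoh1. At 5000 UMIs 70 of 122 cocktail and 107 of 152 vehicle cells with one lay outside these clusters. The quotient therefore cannot decide whether an excess of cells carrying Atoh1 was the whole cause. At 1053 UMIs the quotient of 0.893 (0.594 to 1.33) excluded nothing, and outside these clusters the Atoh1 ratio was 1.68 (1.06 to 2.65) at 1053 UMIs, 1.08 (0.811 to 1.43) at 5000 UMIs and 0.975 (0.801 to 1.19) without thinning. As the whole or a part of the cause, an excess of cells carrying Atoh1 stays open. So do more Atoh1 per cell and an effect of the cocktail on the cells of these clusters.

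The third pattern was single cells in which 1 gene took an outlying share of UMIs (199 gene and cell pairs in 102 cells), among them 47 of 89 cocktail and 28 of 75 vehicle cells of cluster 5 and 1 of 191 and 0 of 144 cells of cluster 3. Doublets would raise the total and the number of genes, yet within cluster 5 the median total was 0.519 times that of the other cells (7148 against 13783 UMIs, though 11058.5 against 11263 in the vehicle library), with 1030 against 3812 genes. A transcribed stretch of 1 chromosome would place such genes side by side, yet 0 of 183 pairs in a cell lay within 1 Mb, against a median of 0 and at most 3 over 1000 reassignments. A heavy load of the Atoh1 vector stays open in cluster 5. There Atoh1 outside the outlying genes was 1.86 times as high per UMI in these cells (1.22 to 2.78 over resampled cells). Per cell it was 0.923 times as high (0.586 to 1.42), so the excess per UMI goes with their lower totals. No Atoh1 UMI was found in 16 of the 75 cells, nor in 18 of the 89 other cells of the cluster. In cluster 17, with 14 of 51 cocktail and 12 of 93 vehicle cells, 23 of the 26 cells had no Atoh1 UMI. The same held for 110 of the 118 other cells of that cluster. The ratio per UMI of 2.04 (0 to 8.03) rests on 5 and 15 UMIs, which leaves a vector load open there too. No biological explanation was tested.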

How the results depend on the processing

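Alternatives leaving out clusters or highest cells, with at least 5000 UMIs, with the Epcam denominator, with clustering without leading genes, with deeper thinning for cycling, and with class weighting for lists and targets were chosen after the results were seen. The rest were set before the data were examined. No paired analysis was possible because each condition has 1 library and cells were not assigned to cultures here. Ratios of single genes are log2 with 0.5 count added per library. Except where construction is named, the cause was not tested.

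Shares were recomputed for the Gal- and Cck-high clusters together and for the hair-cell-, supporting-cell-, interdental- or inner-sulcus-, fibroblast-, glia-, osteoblast- and endothelial-like classes. Single unnamed clusters and the neuron- and macrophage-like classes were not recomputed. None of the recomputed share differences reversed, and 69 of 76 stayed within the main interval. Hair-cell-like cells ranged from -2.89 to -1.40 points, Gal- and Cck-high clusters from 12 to 15.1 and glia-like cells from -9.43 to -7.88. Among Epcam-expressing clusters, a smaller total by construction, hair-cell-like cells were at -2.89 and supporting-cell-like cells at -2.17. With no filter the interdental- or inner-sulcus-like share was at 4.19. The fibroblast-like share was at 1.06 with called doublets kept, 1.31 at Leiden resolution 0.5 and 0.790 with at least 5000 UMIs, with intervals that held 0, as at 2.21 when clustered without leading genes. With at least 5000 UMIs osteoblast-like cells were at -4.46. Supporting-cell-like cells merged into other clusters under 4000 variable genes, resolution 0.5, doublets kept and no filter, osteoblast-like cells under resolution 0.5, doublets kept and clustering without leading genes, and endothelial-like cells under resolution 0.5, so these gave no value.

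Without clusters 5 and 17, 8 of 16 whole-library genes had a counting interval wholly on their side of 0. Hsd17b3 was at -1.81, Il12rb1 at -0.049, Tmbim7 at -0.10, Adamts16 at 0.88, Atoh1 at 0.35, Mxi1 at -0.28 and the inflammatory list at 0.72.

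Without each gene's highest cell, a step that by construction removes genes resting on 1 cell, genes whose whole counting interval lay on their side of 0 numbered 1 of 10 in cluster 12, 5 in cluster 17, 4 in cluster 3, 6 in cluster 5 and 3 in fibroblast-like cells. Adamts16 was at 0.086, Mgat4b at 0.10 and Dnajb12 at 0.30 in cluster 12, Cep85 at -0.043 and Cep57l1 at 0.11 in interdental- or inner-sulcus-like cells, Mxi1 at -0.34, the TGF beta list at 0.034 in cluster 1 and the interferon list at 1.01 in cluster 3. Genes left with under 3 UMIs, such as Krtap15, gave no value.

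With cell classes weighted alike, which by construction uses only classes with at least 50 cells per library, Adgrl4 was at 1.29, Atoh1 at 0.27, Puf60 at 0.31, Mxi1 at -1.44, and the hair bundle list at 0.10, interferon at 0.69, inflammatory genes at 0.64 and cholesterol synthesis at 0.35.

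As a mean of per-cell CPM, Atoh1 was at 0.38 (-0.26 in cluster 17), Puf60 at 0.15, Mxi1 at -1.14, the otic progenitor list at 0.047 and the TGF beta list in cluster 1 at 0.49. The interferon list was at 0.54 in cluster 3, 1.05 in fibroblast-like and -0.17 in interdental- or inner-sulcus-like cells.

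With no filter Sct was at -4.11 in cluster 14, and in interdental- or inner-sulcus-like cells Rgs20 was at -1.98, Stc1 at -0.25 and the TGF beta list at -0.16. With at least 1000 UMIs Rgs20 was at -1.41, Stc1 at -0.37, Acta2 in cluster 12 at -0.42, the otic progenitor list in cluster 1 at -0.13, and 6 of 10 fibroblast-like genes had such an interval. At most 10% mitochondrial UMIs put Acta2 at -0.39. Leiden resolution 0.5 put Apoc3 at -0.41 in cluster 1, Epyc at -0.17 in fibroblast-like cells and Nwd1 at -1.23 in interdental- or inner-sulcus-like cells. With no minimum beyond 1 UMI the otic progenitor list was at -0.88 and the TGF beta list at 0.22 in cluster 1, and supporting cell identity at -0.22 in fibroblast-like cells.

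The share with at least 3 hair cell markers was 0.311 points without thinning and 2.84 points at the median depth. With at least 1 cell cycle UMI the differences were -0.0504 points in the whole library and -3.23 in fibroblast-like cells, and at the median depth the latter was -0.437. Depth limits both counts.

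Of the main list medians 89 of 98 stayed within the spread of random lists around them, and of the other list medians 1639 of 1749. Within the counting interval of their first value stayed 985 of 1154 values of genes within classes, 114 of 142 of whole-library genes and 18 of 27 of Atoh1, Puf60 and Mxi1 in the whole library. The interferon list ranged from 0.69 to 0.87 in the whole library, from 1.05 to 1.31 in fibroblast-like cells and from -0.51 to -0.17 in interdental- or inner-sulcus-like cells. Atoh1 ranged from 0.27 to 0.67. Median-ratio scaling shifted the median of all genes in cluster 17 by 0.10 (log2).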

Other observations

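Of the tests here, the comparison at 1053 UMIs was fixed before its result was seen, and those at 5000 UMIs were chosen afterwards. Mymk (ENSMUSG00000009214, GRCm38 chromosome 2, 27061636 to 27072179, minus strand), which encodes a myoblast fusion protein, was among the leading genes of cluster 12 and of the glia-like cluster 24. A hypothesis was that Mymk transcripts may accompany Atoh1 transcripts cell by cell. In glia-like cells thinned to 1053 UMIs, 1 of 3 cells with an Atoh1 UMI and 31 of 190 without one had a Mymk UMI, a difference of 17 points (-10.8 to 63.1), and 3 cells are too few to decide. At 5000 UMIs the counts were 9 of 11 and 37 of 147, a difference of 56.6 points (26.2 to 71.1). In cluster 12 the difference was -2.17 points (-24.7 to 29.8) at 1053 UMIs and -7.06 points (-23.0 to 7.46) at 5000 UMIs. No association was detectable in cluster 12, and the hypothesis stays open in glia-like cells.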
